A study of Mus musculus with 54 samples.

How the data were processed

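Messenger RNA was sequenced from testis and ovary of adult mice in 54 libraries. Per the labels' protocols, RNA was extracted with TRIZOL and libraries came from a stranded ligation kit read at 100 nt. The submitters list bcl2fastq 2.20, FastQC 1.19, TopHat2 2.1.1, Bowtie2 2.4.5, SAMtools 1.13, featureCounts 2.0.3 and DESeq2 1.32.0 on genome build mm39. The strand setting and the annotation of the counting step are not given in the sources used here, so antisense and overlapping genes are treated as uncertain. The authors deposited whole-number counts per gene, not normalised, in 1 table of 26264 entries per tissue. Of these, 133 have no gene ID, holding 0.319 to 0.377% of counts in testis libraries and 0.0591 to 0.0861% in ovary libraries. They stayed in the library totals and, where they passed the expression filter, in the tests, but could not be named.

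Columns were matched to samples by their codes, and groups came from the labels. Counts of genes in replicates were compared by chi-square, and no libraries agreed within sampling noise (lowest value per gene 3.24, next 4.08). Gene IDs were looked up in a RefSeq gene table of GRCm38.p6, where 26083 of 26131 IDs matched. It differs from mm39, so no coordinates are given and it served only for names and gene order.

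Here the tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test with robust estimates on the deposited counts. It used TMM factors, the expression filter of edgeR with a minimum count of 10, Benjamini-Hochberg adjustment and a threshold of 0.05. A prior count of 2 was used for log2 CPM, not for log2 fold changes. The 9 F1 libraries of a tissue shared a fit, the 18 F2 libraries another, and comparisons between generations used all 27. There were 14 comparisons with control libraries and 12 others. Comparisons with control share their controls within a generation, so overlaps of calls were set beside 20 simulations of unchanged groups.

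Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list, and adjusted over the lists of a comparison. In all 37 lists were fixed before the data were examined, and 27 in testis and 28 in ovary had the minimum of 5 tested genes. Of 1 list, 0 of its 15 genes are in the tables, and it was not analysed here. Another list, of circadian clock and cold-shock genes, was added after the data were seen and tested by itself.

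Genes are named by a rule fixed before the data were examined. They passed the threshold, had a mean of at least 1 CPM and a symbol that is not a predicted name, and the libraries of the compared groups did not overlap. The 10 largest changes each way were taken for F1 and for both parents at dose 2, 5 for the other F2 comparisons with control and 3 for the remaining comparisons. Where fewer than 3 qualified, the 5 smallest p are given as well. Up to 4 members with the smallest p are named for each list past the threshold. Antisense genes, predicted genes and genes known to have close relatives are called uncertain, from knowledge of the families and not from a measure of sequence similarity. Some genes that the rule selects are not reported here.

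The alternatives fixed beforehand were DESeq2, RLE size factors, no low-count filter, the replicate letter as a block, each library left out in turn, other libraries in the fit and an estimated correlation. Settings that leave out several libraries were added after the data were seen. A setting with control parents library B as the only testis F2 control was fitted too and set aside before its counts were examined, because its reason, that libraries A and C stand apart, did not hold. Deviations from the group means were correlated between libraries of the same letter. In ovary F1 dose 1 against control the correlations were 0.188, 0.201 and 0.35, all above 0.1, so the letters were taken to pair these samples. The labels do not say what the letters share.

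The steps were tested on simulated counts with 200 changed genes. The test recovered 35.8, 70.1 and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold in testis F1 dose 2 (18923 genes), with 11 unchanged genes called. It recovered 43.3, 70.1 and 90.9% in testis both parents dose 2 (19241 genes; 11 called), 1.49, 35.8 and 75.8% in ovary F1 dose 2 (17168 genes; 5 called) and 22.4, 58.2 and 89.4% in ovary both parents dose 2 (17454 genes; 3 called). DESeq2 called 42, 23, 51 and 18 unchanged genes in these, and recovered 74.6, 76.1, 65.7 and 65.7% of genes changed 2-fold.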

Results

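RNA was sequenced from adult mouse testis and ovary in 54 libraries, 27 per tissue. In the first generation (F1), animals received from 8.5 days post-coitum drinking water with a mixture of ibuprofen, 2-hydroxyibuprofen, diclofenac and ethinyl-estradiol, a synthetic oestrogen. Dose 1 held 11.3, 90, 22.5 and 2.25 ng/L of these compounds in that order, and dose 2 held 113, 225, 112 and 45 ng/L. Control water held 0.001% ethanol. Males were sampled at 10 weeks and females at 8 weeks. The second generation (F2), labelled as untreated, came from crosses in which neither parent, the mother, the father or both parents belonged to a dose group. Each tissue had 9 groups of 3 libraries (A, B and C). These were F1 control, dose 1 and dose 2, and F2 from control parents, mother dose 1, mother dose 2, father dose 1, father dose 2 and both parents dose 2. Cross codes were read with the male first, which the table headers themselves do not state. Nothing says that the replicates came from separate litters, so p-values measure only the spread between these samples. Total counts per library were 31.8 to 46.4 M in testis (median 37.7 M) and 35.6 to 102 M in ovary (median 43.8 M). Counts scaled by library size (CPM) are given as mean ± SD and log2 fold changes as value ± SE, with n = 3 libraries per group. A value with ± after a gene name alone is such a log2 fold change. Xist, the X-inactivation transcript, had 19 to 82 counts in testis libraries and 22489 to 101179 in ovary libraries. Y-linked Ddx3y had 352 to 646 counts in testis libraries and 0 in all ovary libraries.

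**Figure D1:**
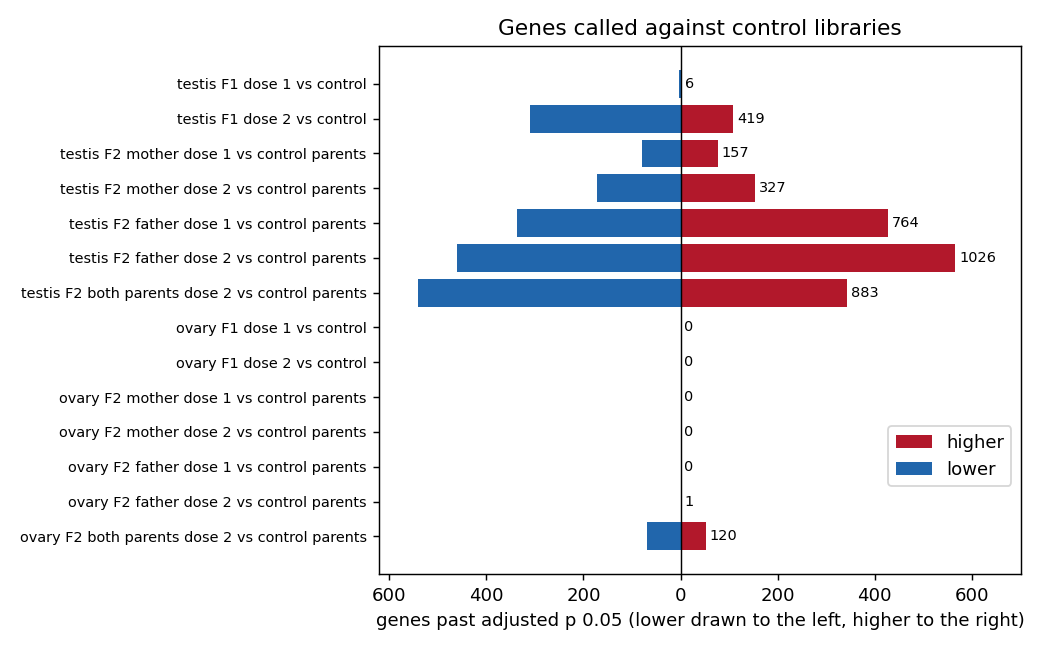
Genes past an adjusted p of 0.05 in each of the 14 comparisons with control libraries, edgeR's quasi-likelihood test. Bars to the right count genes that were higher and bars to the left genes that were lower, with the total printed beside them: testis totals run from 6 to 1026, and 5 of the 7 ovary totals are 0.

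In the F1 testis, dose 1 was compared with controls. Inherited family differences were not tested in F1. Kcnk2 (Entrez 16526), a potassium channel gene, rose 3.17-fold (log2 1.66 ± 0.20, adjusted p = 0.0165). Grm4 (Entrez 268934), a metabotropic glutamate receptor, fell 11.9-fold (log2 -3.57 ± 0.31, adjusted p = 0.00129). The sugar-phosphate transporter Slc37a1 fell 2.9-fold (log2 -1.54 ± 0.12, adjusted p = 0.00129), the zinc-finger gene Zfp354b (uncertain) 2.55-fold (log2 -1.35 ± 0.14, adjusted p = 0.00521) and the axonemal dynein Dnah8 1.84-fold (log2 -0.88 ± 0.096, adjusted p = 0.00834). Immediate early genes, transcribed within minutes of a stimulus, were lower (adjusted p = 8.48e-04, adjusted p = 0.889 with an estimated correlation). Jun -0.57 ± 0.12, Junb -1.35 ± 0.35 and Fos -3.69 ± 1.10 were among its 20 members, of which 0 passed over all genes and 5 adjusted over the list alone. Macrophage genes were also lower (adjusted p = 0.0127, adjusted p = 0.889 with an estimated correlation). 0 of 20 members passed over all genes and 0 adjusted over the list alone. In all, 6 of 18923 genes passed (2 higher, 4 lower), and 1618 had an unadjusted p under 0.05 against 946 by chance. The count was 315, 10 and 22 without F1 dose 1 A, B and C, and 3 and 12 without F1 control A and C. It was 16 with only the 6 libraries compared, 27 with all 27, 13 without the low-count filter and 139 by DESeq2.

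At dose 2, the synaptic adhesion gene Tenm2 (Entrez 23964) rose 4.12-fold (log2 2.04 ± 0.38, adjusted p = 0.0445) in the F1 testis. The mechanosensitive channel Piezo1 rose 1.91-fold (log2 0.93 ± 0.14, adjusted p = 0.0178), the chromatin remodeller Chd1l 1.99-fold (log2 0.99 ± 0.17, adjusted p = 0.035) and the paraspeckle RNA Neat1 1.82-fold (log2 0.86 ± 0.12, adjusted p = 0.0141). Stk32a rose 2.16-fold, Rin2 1.81-fold and Ppp1r16b 1.76-fold. Grm4 fell 7.48-fold (log2 -2.90 ± 0.29, adjusted p = 0.00292), Zfp354b (uncertain) 3.19-fold (log2 -1.67 ± 0.14, adjusted p = 0.00145) and the cytochrome P450 gene Cyp4f15 (uncertain) 4.35-fold (log2 -2.12 ± 0.25, adjusted p = 0.00811). The small RNA Bc1 (uncertain) fell 4.84-fold (log2 -2.27 ± 0.33, adjusted p = 0.0261) and the prohormone convertase Pcsk1 3.36-fold (log2 -1.75 ± 0.34, adjusted p = 0.043). Decreases of Mogat1 4.49-fold, Wfdc17 (uncertain) 3.98-fold, Defb45 (uncertain) 2.89-fold and Apof 2.77-fold also passed. Values of Hmga1b (3.08-fold higher), Tmsb15b1 (5.01-fold lower), Zfhx2os (2.12-fold higher) and BC048644 (1.83-fold higher) are uncertain, because reads may be shared with related or overlapping genes.

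Ribosomal protein genes in the F1 dose 2 testis were lower (adjusted p = 7.66e-16, adjusted p = 0.678 with an estimated correlation). Rpl4 -0.61 ± 0.11 and Rps27l -1.23 ± 0.23 were among its 84 members, of which 4 passed over all genes and 43 adjusted over the list alone. Many of them have processed pseudogenes that can take their reads, and the list median was -0.47. Round spermatid genes were lower (adjusted p = 0.00986, adjusted p = 0.678 with an estimated correlation). Actl7b -0.39 ± 0.083 and Pgk2 -0.34 ± 0.095 were among its 22 members, of which 1 passed over all genes and 2 adjusted over the list alone. Extracellular matrix genes were higher (adjusted p = 0.00131, adjusted p = 0.678 with an estimated correlation). Col6a1 0.63 ± 0.19 and Lamb1 0.37 ± 0.10 were among its 30 members, of which 0 passed over all genes and 11 adjusted over the list alone. Peritubular and smooth muscle genes were higher (adjusted p = 0.00986, adjusted p = 0.678 with an estimated correlation). Myh11 0.36 ± 0.075 was among its 13 members, of which 1 passed over all genes and 2 adjusted over the list alone. In all, 419 of 18923 genes passed (109 higher, 310 lower), and 96 of these changed at least 2-fold. Of the 4 genes lower at dose 1, 3 were also lower at dose 2. Independent lists would share 0.0655, and groups simulated without an effect shared 0. Neither value allows for control libraries that deviate, so part or all of the sharing may come from the shared controls. The count was 16, 6 and 223 without F1 dose 2 A, B and C, and 12, 126 and 39 without F1 control A, B and C. It was 1677 without both control C and dose 1 A, the libraries with the highest Prm1 and Tnp1 CPM, a setting chosen after seeing the data. It was 2132 with only the 6 libraries compared, 1315 with all 27 and 1890 by DESeq2.

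The doses differed from each other in the F1 testis at 43 genes (17 higher and 26 lower at dose 2). Slc37a1 was 2.62-fold (log2 1.39 ± 0.12, adjusted p = 0.00234) higher at dose 2, as were Piezo1, 2.06-fold (log2 1.04 ± 0.14, adjusted p = 0.0211), and the cilia gene Rsph1, 1.69-fold (log2 0.76 ± 0.10, adjusted p = 0.0279). Kcnk2 was 2.85-fold (log2 -1.51 ± 0.20, adjusted p = 0.0211) lower at dose 2, Cyp4f15 (uncertain) 3.81-fold (log2 -1.93 ± 0.25, adjusted p = 0.0211) lower and the RNase P RNA Rpph1 3.77-fold (log2 -1.91 ± 0.24, adjusted p = 0.0211) lower. The count was 77, 23 and 16 without F1 dose 1 A, B and C, and 4, 3 and 17 without F1 dose 2 A, B and C. It was 3 with only the 6 libraries compared, 75 without the low-count filter and 1223 by DESeq2.

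In the F2 testis, each cross with an exposed parent was compared with F2 from control parents. In total 23 genes passed in all 5 crosses, 15 higher and 8 lower, and those named here were chosen after their values were seen. Klb (Entrez 83379), a co-receptor for endocrine fibroblast growth factors, rose in every cross (log2 2.85 to 3.45). The dynactin subunit Dctn3 (log2 0.94 to 1.91), the spermatid kinase Tssk5 (log2 0.45 to 0.55) and Mroh9 (log2 0.37 to 0.56) also rose in all 5. So did the chemokine Ccl27a (log2 0.67 to 1.45), which has near-identical copies and is uncertain. Dctn3, Galt and Ccl27a lie close together in the gene order of the GRCm38.p6 table. The transcription factor Egr1 (log2 -2.02 to -0.97), the macrophage chemokine receptor Cx3cr1 (log2 -1.67 to -1.02), the amino acid transporter Slc7a5 (log2 -0.69 to -0.40) and Amotl2 (log2 -1.25 to -0.72) fell in all 5. Dab2 (log2 -0.68 to -0.45), Clstn1 (log2 -0.50 to -0.43), Mtss2 (log2 -0.88 to -0.44) and Bysl (log2 -0.40 to -0.34) fell as well. The transcript 9630028B13Rik was higher (log2 4.75 to 5.95), but it and the other predicted or multi-copy genes of this set are uncertain. Independent lists would share 7.15e-06 higher and 8.47e-06 lower genes, and 20 simulations without an effect shared 0. Neither value allows for control libraries that deviate. The same 3 control libraries served each cross and are too few to split, so part or all of the excess may come from them.

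With only the mother at dose 1, Klb rose 9.98-fold (log2 3.32 ± 0.32, adjusted p = 1.97e-04), at 12.5 ± 3.85 against 1.25 ± 0.433 CPM. The cytokine receptor gene Tnfrsf12a rose 4.13-fold (log2 2.04 ± 0.25, adjusted p = 7.09e-04), otoferlin (Otof) 5.19-fold (log2 2.38 ± 0.44, adjusted p = 0.0234), the lymphocyte gene Crtam 6.49-fold (log2 2.70 ± 0.57, adjusted p = 0.0473) and Dctn3 3.04-fold (log2 1.61 ± 0.21, adjusted p = 0.00255). Libraries A, B and C of this group stood at 22.9, 2.88 and 25.6 CPM of Crtam and 5.91, 1.67 and 6.61 of Otof, with B near the controls (2.47 to 2.82 and 0.743 to 1.23). Egr1 fell 4.06-fold (log2 -2.02 ± 0.28, adjusted p = 0.00295) and Tet1, an enzyme that oxidises methylated cytosine, 2.63-fold (log2 -1.40 ± 0.27, adjusted p = 0.0224). C1qtnf2 fell 5.03-fold (log2 -2.33 ± 0.47, adjusted p = 0.0315), Dmkn 3.39-fold (log2 -1.76 ± 0.40, adjusted p = 0.0441) and Ceacam10 (uncertain) 4.77-fold (log2 -2.25 ± 0.36, adjusted p = 0.00551). Round spermatid genes were higher (adjusted p = 0.00479, adjusted p = 0.509 with an estimated correlation). 0 of 22 members passed over all genes and 1 adjusted over the list alone. Ribosomal protein genes were higher (adjusted p = 0.00333, adjusted p = 0.713 with an estimated correlation). 0 of 85 members passed over all genes and 0 adjusted over the list alone. Extracellular matrix genes were lower (adjusted p = 0.00333, adjusted p = 0.509 with an estimated correlation). Nid1 -0.51 ± 0.12 was among its 30 members, of which 1 passed over all genes and 2 adjusted over the list alone. Lipid storage and beta-oxidation genes were lower (adjusted p = 0.00738, adjusted p = 0.509 with an estimated correlation). 0 of 27 members passed over all genes and 5 adjusted over the list alone. Leydig steroidogenesis genes were lower (adjusted p = 0.0198, adjusted p = 0.509 with an estimated correlation). Nr5a1 -0.52 ± 0.12 was among its 20 members, of which 1 passed over all genes and 1 adjusted over the list alone. The peritubular, endothelial, oestrogen-responsive and immediate early lists were lower too (adjusted p = 0.0198 for the first 3 and 0.0435 for the last, adjusted p = 0.509 with an estimated correlation for each). In all, 157 of 19241 genes passed (77 higher, 80 lower). The count was 27 and 46 without mother dose 1 A and C, and 29, 785 and 44 without control parents A, B and C. It was 98 with all 27 libraries and 645 by DESeq2.

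With only the mother at dose 2, Cyp17a1 (-0.51 ± 0.096, adjusted p = 0.0141), which makes androgen precursors, fell. So did Star (-0.51 ± 0.11, adjusted p = 0.0259), which carries cholesterol into mitochondria. The Leydig steroidogenesis genes were lower (adjusted p = 2.53e-08, adjusted p = 0.043 with an estimated correlation). Vcam1 -0.66 ± 0.14 and Prlr -0.64 ± 0.14 were among its 20 members, of which 5 passed over all genes and 13 adjusted over the list alone. Of lists fixed beforehand, only this list held with an estimated correlation in the 14 comparisons, without adjustment over them. Control parents had the highest Leydig list mean of the testis groups (5.12 log2 CPM). Macrophage genes were lower (adjusted p = 5.45e-05, adjusted p = 0.0739 with an estimated correlation). Cx3cr1 -1.46 ± 0.19, Csf1r -0.87 ± 0.12 and Lyz2 -0.64 ± 0.13 were among its 20 members, of which 3 passed over all genes and 7 adjusted over the list alone. Lipid storage and beta-oxidation genes were lower (adjusted p = 8.23e-06, adjusted p = 0.122 with an estimated correlation). Acadl -0.51 ± 0.098 and Acadm -0.50 ± 0.11 were among its 27 members, of which 4 passed over all genes and 9 adjusted over the list alone. Extracellular matrix genes were lower (adjusted p = 6.03e-07, adjusted p = 0.158 with an estimated correlation). Lamc1 -0.59 ± 0.12 was among its 30 members, of which 2 passed over all genes and 11 adjusted over the list alone. Antioxidant genes were lower (adjusted p = 3.89e-04, adjusted p = 0.134 with an estimated correlation). Gpx1 -0.58 ± 0.097 was among its 27 members, of which 3 passed over all genes and 6 adjusted over the list alone. Meiotic spermatocyte genes were higher (adjusted p = 6.37e-04, adjusted p = 0.134 with an estimated correlation). Hormad1 0.39 ± 0.084 and Sycp1 0.51 ± 0.12 were among its 27 members, of which 2 passed over all genes and 3 adjusted over the list alone.

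Of single genes with the mother at dose 2, Klb rose 10.9-fold (log2 3.45 ± 0.32, adjusted p = 2.05e-04), Otof 6.53-fold (log2 2.71 ± 0.44, adjusted p = 0.00917), the synaptic gene Cplx1 2.19-fold and Dctn3 2-fold (log2 1.00 ± 0.21, adjusted p = 0.0265). The receptor kinase Ros1 fell 7.71-fold (log2 -2.95 ± 0.54, adjusted p = 0.0172), C1qtnf2 6.39-fold (log2 -2.67 ± 0.48, adjusted p = 0.0128) and Olfml3 3.56-fold (log2 -1.83 ± 0.37, adjusted p = 0.0216). The intestinal-type phosphatases Alpi (3.55-fold lower) and Akp3 (2.85-fold lower) are related in sequence and uncertain. The other 7 lists past the threshold were round spermatids (higher) and the peritubular, endothelial, prostaglandin, oestrogen-responsive, ribosomal protein and cholesterol synthesis lists (lower). Their adjusted p ran from 4.84e-05 to 0.0254, and from adjusted p = 0.0608 to 0.722 with an estimated correlation. In all, 327 of 19241 genes passed (154 higher, 173 lower). The count was 167, 134 and 76 without mother dose 2 A, B and C, and 48, 1800 and 40 without control parents A, B and C. It was 202 with only the 6 libraries compared and 947 by DESeq2.

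With only the father at dose 1, Mog (Entrez 17441), a myelin glycoprotein gene, rose to 6.41 ± 1.74 against 0.0335 ± 0.0385 CPM (adjusted p = 9.52e-07). Mrs2 (Entrez 380836), a mitochondrial magnesium channel, fell 8.92-fold (log2 -3.16 ± 0.21, adjusted p = 9.52e-07), at 5.51 ± 2.28 against 48.7 ± 0.925 CPM. Klb rose 7.81-fold (log2 2.97 ± 0.32, adjusted p = 1.35e-04), Faim2 4.28-fold and Galt, an enzyme of galactose breakdown, 4.01-fold (log2 2.00 ± 0.23, adjusted p = 7.84e-05). Cyp21a1 (uncertain), a steroid hydroxylase, fell 4.14-fold (log2 -2.05 ± 0.52, adjusted p = 0.0483), Ceacam10 (uncertain) 7.75-fold (log2 -2.95 ± 0.38, adjusted p = 2.57e-04) and the phosphatase Ptprt 6.2-fold (log2 -2.63 ± 0.66, adjusted p = 0.0381). Control parents stood at 4.11, 1.02 and 5.21 CPM of Ptprt in A, B and C. Apol7e (4.09-fold higher) is uncertain as a member of a multi-copy family. BC023719, poorly annotated and uncertain, was lower, at 0.105 ± 0.109 against 2.78 ± 1.52 CPM. Leydig genes were lower (adjusted p = 5.43e-05, adjusted p = 0.134 with an estimated correlation). Star -0.70 ± 0.11, Hsd17b3 -0.89 ± 0.17 and Prlr -0.68 ± 0.14 were among its 20 members, of which 6 passed over all genes and 8 adjusted over the list alone. Macrophage genes were lower (adjusted p = 5.43e-05, adjusted p = 0.134 with an estimated correlation). Lyz2 -1.12 ± 0.14 and Cx3cr1 -1.15 ± 0.19 were among its 20 members, of which 5 passed over all genes and 9 adjusted over the list alone. Lipid genes were lower (adjusted p = 1.09e-04, adjusted p = 0.301 with an estimated correlation). Cd36 -0.89 ± 0.15 was among its 27 members, of which 4 passed over all genes and 9 adjusted over the list alone. Extracellular matrix genes were lower (adjusted p = 1.09e-04, adjusted p = 0.378 with an estimated correlation). 3 of 30 members passed over all genes and 5 adjusted over the list alone. Another 6 lists (antioxidant, cholesterol synthesis, endothelial, peritubular, oestrogen-responsive and xenobiotic metabolism) were lower. Their adjusted p ran from 0.014 to 0.0296, and from adjusted p = 0.207 to 0.385 with an estimated correlation. Meiotic genes were higher (adjusted p = 0.0296, adjusted p = 0.378 with an estimated correlation). 2 of 27 members passed over all genes and 4 adjusted over the list alone. In all, 764 of 19241 genes passed (427 higher, 337 lower). The count was 247 and 271 without father dose 1 B and C, and 224, 1595 and 285 without control parents A, B and C. It was 1264 by DESeq2.

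With only the father at dose 2, Klb rose 10.7-fold (log2 3.42 ± 0.32, adjusted p = 2.34e-04) and podoplanin (Pdpn) fell 2.55-fold (log2 -1.35 ± 0.24, adjusted p = 0.00693). The zinc-finger gene Zfp493 was 3.87-fold higher, Cldn34d 3.14-fold higher and the small nuclear RNA Rn7sk 2.74-fold higher, all with related copies and uncertain. Zfp981, Zfp991 and Zfp992 were 14.9-fold, 12.8-fold and 5.02-fold lower, but they are near-identical paralogues and uncertain. So are the antisense genes Cd55os (2.84-fold higher) and Ccdc42os (3.31-fold lower). Leydig genes were lower (adjusted p = 1.92e-05, adjusted p = 0.0879 with an estimated correlation). Cyp17a1 -0.50 ± 0.096, Nr5a1 -0.57 ± 0.12 and Cyp11a1 -0.64 ± 0.14 were among its 20 members, of which 5 passed over all genes and 9 adjusted over the list alone. Lipid genes were lower (adjusted p = 2.10e-05, adjusted p = 0.247 with an estimated correlation). 5 of 27 members passed over all genes and 14 adjusted over the list alone. Antioxidant genes were lower (adjusted p = 1.60e-04, adjusted p = 0.247 with an estimated correlation). Gpx1 -0.68 ± 0.098 and Sod3 -0.55 ± 0.11 were among its 27 members, of which 5 passed over all genes and 7 adjusted over the list alone. Sertoli cell genes, of the nurse cells of the tubule, were lower (adjusted p = 4.01e-04, adjusted p = 0.304 with an estimated correlation). Gata4 -0.42 ± 0.091 and Inha -0.43 ± 0.12 were among its 25 members, of which 4 passed over all genes and 5 adjusted over the list alone. Meiotic genes were higher (adjusted p = 0.00624, adjusted p = 0.254 with an estimated correlation). Sycp1 0.58 ± 0.12 and Msh4 0.43 ± 0.10 were among its 27 members, of which 4 passed over all genes and 7 adjusted over the list alone. The other 6 lists (extracellular matrix, endothelial, peritubular, macrophage, ribosomal protein and elongating spermatid) were lower. Their adjusted p ran from 1.60e-04 to 0.0435, and from adjusted p = 0.0879 to 0.632 with an estimated correlation. In all, 1026 of 19241 genes passed (566 higher, 460 lower). The count was 75 and 105 without father dose 2 A and B, and 82, 3122 and 88 without control parents A, B and C. It was 458 with only the 6 libraries compared and 1879 by DESeq2.

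With both parents at dose 2, Leydig steroidogenesis genes were lower (adjusted p = 7.14e-07, adjusted p = 0.084 with an estimated correlation). Cyp11a1 -0.80 ± 0.14, Nr5a1 -0.72 ± 0.12, Star -0.69 ± 0.11 and Cyp17a1 -0.63 ± 0.097 were among its 20 members, of which 9 passed over all genes and 13 adjusted over the list alone. Cholesterol synthesis genes were lower (adjusted p = 2.07e-05, adjusted p = 0.13 with an estimated correlation). Dhcr7 -0.66 ± 0.13 and Ebp -0.62 ± 0.14 were among its 24 members, of which 6 passed over all genes and 11 adjusted over the list alone. Lipid genes were lower (adjusted p = 2.86e-06, adjusted p = 0.124 with an estimated correlation). Scd2 -0.71 ± 0.12 was among its 27 members, of which 6 passed over all genes and 16 adjusted over the list alone. Oestrogen receptor and responsive genes were lower (adjusted p = 8.51e-04, adjusted p = 0.103 with an estimated correlation). Esr1 -0.82 ± 0.16 was among its 28 members, of which 2 passed over all genes and 6 adjusted over the list alone. Xenobiotic metabolism genes were lower (adjusted p = 0.014, adjusted p = 0.199 with an estimated correlation). Gstm1 -0.99 ± 0.16 and Ephx1 -0.68 ± 0.13 were among its 25 members, of which 4 passed over all genes and 5 adjusted over the list alone. Macrophage genes were lower (adjusted p = 5.64e-04, adjusted p = 0.124 with an estimated correlation). Cx3cr1 -1.67 ± 0.19 and Csf1r -0.91 ± 0.12 were among its 20 members, of which 4 passed over all genes and 6 adjusted over the list alone. Sertoli cell genes were lower (adjusted p = 2.85e-04, adjusted p = 0.199 with an estimated correlation). Gata4 -0.57 ± 0.092 was among its 25 members, of which 2 passed over all genes and 6 adjusted over the list alone. Meiotic genes were higher (adjusted p = 2.85e-04, adjusted p = 0.13 with an estimated correlation). Hormad1 0.41 ± 0.084 and Syce2 0.71 ± 0.17 were among its 27 members, of which 4 passed over all genes and 6 adjusted over the list alone. Round spermatid genes were higher (adjusted p = 0.0111, adjusted p = 0.349 with an estimated correlation). Catsper4 0.44 ± 0.088 was among its 22 members, of which 1 passed over all genes and 5 adjusted over the list alone. Fat markers were higher (adjusted p = 0.0434, adjusted p = 0.202 with an estimated correlation; 0 over all genes and 4 adjusted over the list alone). The fat list had a mean log2 CPM of 0.14, 0.0712 and -0.926 in libraries A, B and C and -1.11 to -0.81 in control parents. The epididymis list stood at -2.06 in A and in B against -2.94 to -2.62 in control parents. The peritubular, extracellular matrix, endothelial and antioxidant lists were lower, with adjusted p from 2.82e-05 to 0.0057, and from adjusted p = 0.103 to 0.199 with an estimated correlation.

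Among single genes with both parents at dose 2, Klb rose 7.19-fold (log2 2.85 ± 0.32, adjusted p = 3.89e-04), the sodium channel Scn8a 2.81-fold (log2 1.49 ± 0.26, adjusted p = 0.00585) and cystathionine gamma-lyase (Cth) 3.59-fold (log2 1.84 ± 0.48, adjusted p = 0.0406). Otof rose 4.34-fold (log2 2.12 ± 0.44, adjusted p = 0.0171) and Tnfrsf12a 3.05-fold (log2 1.61 ± 0.25, adjusted p = 0.00234). Increases of Arhgap40 3.74-fold and Sgca 2.52-fold passed too. Cx3cr1 fell 3.19-fold (log2 -1.67 ± 0.19, adjusted p = 2.04e-04), Egr1 2.67-fold (log2 -1.42 ± 0.27, adjusted p = 0.0109), Ceacam10 (uncertain) 6.01-fold (log2 -2.59 ± 0.36, adjusted p = 0.00101) and Kcnk2 2.99-fold (log2 -1.58 ± 0.40, adjusted p = 0.0393). Decreases of Ptprt 6.05-fold, Slc22a22 (uncertain) 4.63-fold, Wdr49 3.55-fold, Slc47a1 2.8-fold and Fetub 2.79-fold passed as well. Of Egr1 and Ptprt, control parents B held 5.57 and 1.02 CPM, near the 5.14 and 0.821 of library A of this group. Cd55os (2.83-fold higher), Tmsb15l (2.33-fold higher) and Ccdc42os (2.89-fold lower) are uncertain. Crisp1, an epididymal secretory gene, was at least 32.9-fold higher against a floor of 3 counts per control library. It had 167, 137 and 4 counts in libraries A, B and C and 0 in the controls. In all, 883 of 19241 genes passed (342 higher, 541 lower). The count was 190 without both parents dose 2 B, and 116, 2416 and 179 without control parents A, B and C. A setting without A and B, chosen after seeing the data, leaves only library C, so its count is not given. The count was 120 with only the 6 libraries compared and 1564 by DESeq2.

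**Figure D2:**
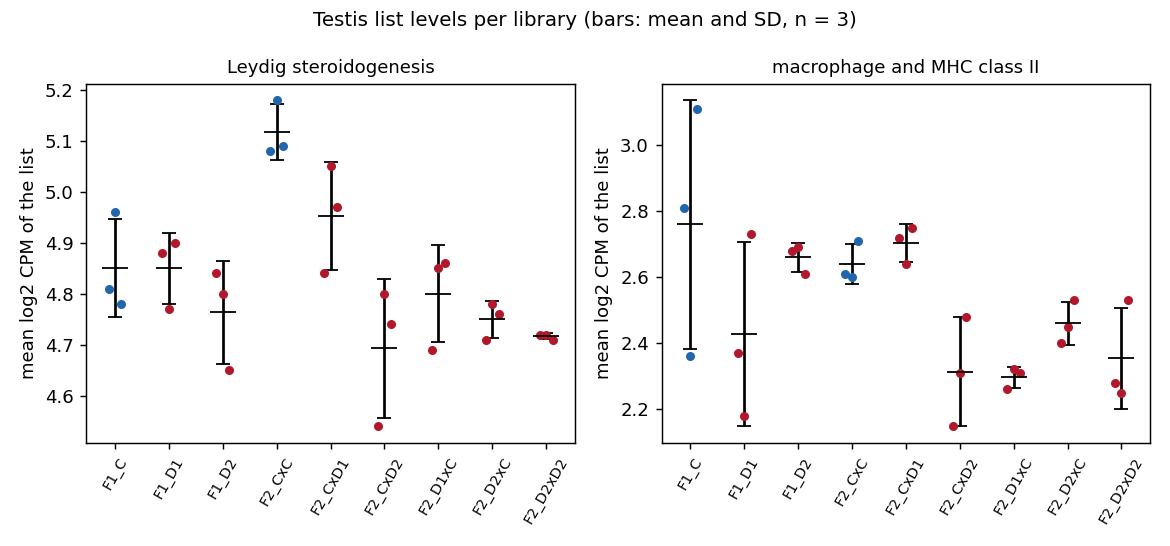
Mean log2 CPM of the Leydig steroidogenesis list (left) and of the macrophage list (right) in each testis library, by group, with group codes written male x female (C control, D1 dose 1, D2 dose 2). Points are libraries (blue for control groups, red for others) and bars show mean and SD (n = 3): the Leydig mean is 5.12 in F2 from control parents, 4.85 in F1 controls and 4.69 to 4.95 in the 5 crosses with an exposed parent.

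Exposed father was tested directly against exposed mother. At dose 1, 223 genes differed (98 higher and 125 lower with an exposed father). Mog stood at 6.41 ± 1.74 CPM with an exposed father and 0.0563 ± 0.075 CPM with an exposed mother (adjusted p = 1.27e-06), and Mrs2 was 8.42-fold (log2 -3.07 ± 0.21, adjusted p = 1.27e-06) lower. Phyhip was 18.1-fold lower. Ifi204 (4.78-fold higher), Apol7e (5.85-fold higher) and Zfp990 (16.7-fold lower) have close paralogues and are uncertain. At dose 2, 21 genes differed. Mfap5 was 2.81-fold (log2 1.49 ± 0.25, adjusted p = 0.0295) higher with an exposed father, Cmc1 2.44-fold higher and Myo5c 2.24-fold higher. Cplx1 was 2.7-fold (log2 -1.43 ± 0.20, adjusted p = 0.00988) lower, Ccr4 2.58-fold lower and Arfgef3 2.16-fold lower. The dose 1 count was 89 and 115 without mother dose 1 A and C, and 79 and 106 without father dose 1 B and C, 707 with only the 6 libraries compared, and 509 by DESeq2. The dose 2 count was 47, 3 and 0 without mother dose 2 A, B and C, and 5, 0 and 9 without father dose 2 A, B and C, 61 with only the 6, and 88 by DESeq2. The effect of both dose 2 parents differed from the sum of the single-parent effects at 94 genes. Adgrg7 lay 4.18-fold (log2 -2.06 ± 0.19, adjusted p = 1.12e-05) below that sum, Cst9 (uncertain) 2.48-fold below and Psmg4 2.29-fold below. C1qtnf2 lay 12.1-fold (log2 3.60 ± 0.65, adjusted p = 0.0219) above it, as did the kallikrein paralogues Klk1b27 and Klk1b24, which are uncertain. The interaction count was 39 and 29 without mother dose 2 B and C, and 35, 31 and 179 without father dose 2 A, B and C, and 57, 31 and 165 without both parents dose 2 A, B and C, and 26, 1047 and 37 without control parents A, B and C. It was 57 with only its 12 libraries and 462 by DESeq2.

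Generations were compared within the testis. F2 from control parents differed from F1 controls, both without the mixture, at 2828 of 19467 genes (1195 higher, 1633 lower). No label separates generation from the time and handling of the samples. Galntl6 was 33.1-fold (log2 5.05 ± 1.51, adjusted p = 0.0329) higher in F2, Dapp1 8.64-fold higher and the mitochondrial coactivator Ppargc1a 7.17-fold higher. The coactivator Wwtr1 was 7.67-fold (log2 -2.94 ± 0.67, adjusted p = 0.00985) lower and Mogat1 7.16-fold lower. Tmsb15b1 was 12.2-fold lower and uncertain. The effect of dose 2 in F2 from dose 2 parents differed from that in exposed F1 at 2070 genes. Tnfrsf12a was relatively 7.43-fold (log2 2.89 ± 0.61, adjusted p = 0.00785) higher in F2. Cypt15 (5.07-fold higher) and Ssxb3 (3.44-fold higher) come from multi-copy families and are uncertain. The bile transporter Abcb4 was relatively 4.85-fold (log2 -2.28 ± 0.47, adjusted p = 0.00632) lower, Lmo7 3.25-fold lower and Hmga1b 5.63-fold lower, the last uncertain. The count for the control groups was 574 without F1 control C, and 1084 and 1007 without control parents A and C. The count for the dose 2 effect was 923 and 829 without F1 dose 2 A and B, and 3420 and 814 without both parents dose 2 A and C, and 703 without F1 control C, and 1030 and 922 without control parents A and C. It was 543 with only the 12 libraries of these groups.

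Fold changes of genes in exposed F1 were correlated with those in F2 at the same dose, over 10 relations in both tissues. Genes are not independent, so each r was compared with 100 splits of the libraries. In testis, Pearson's r across 18838 genes ran from -0.107 to 0.00112 and Spearman's rho from -0.141 to 0.082. In ovary, r across 17026 genes ran from -0.222 to 0.242 and rho from -0.389 to 0.202. The smallest permutation p was 0.07, for ovary dose 1 against mother dose 1 (adjusted p = 0.7), and none of the 10 relations passed.

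In the ovary of F1 females at dose 1, oocyte genes were lower (adjusted p = 1.74e-09, adjusted p = 0.909 with an estimated correlation). Ooep -0.68 ± 0.22 and Zar1 -0.62 ± 0.23 were among its 30 members, of which 0 passed over all genes and 0 adjusted over the list alone. Ribosomal protein genes were lower (adjusted p = 1.28e-14, adjusted p = 0.909 with an estimated correlation). 0 of 83 members passed over all genes and 0 adjusted over the list alone. Endothelial genes were higher (adjusted p = 3.37e-05, adjusted p = 0.909 with an estimated correlation). Flt1 0.76 ± 0.17 and Kdr 0.73 ± 0.20 were among its 16 members, of which 0 passed over all genes and 2 adjusted over the list alone. Cholesterol synthesis genes were higher (adjusted p = 0.0205, adjusted p = 0.984 with an estimated correlation). 0 of 25 members passed over all genes and 1 adjusted over the list alone. The fat, oviduct, peritubular and immediate early lists were lower, with adjusted p from 0.00834 to 0.0205, and from adjusted p = 0.766 to 0.984 with an estimated correlation. Heat shock genes did not pass (adjusted p = 0.0663) but were lower with the replicate letter as a block (adjusted p = 0.00774, adjusted p = 0.984 with an estimated correlation and no block). Control library A held 144 CPM of the oviduct gene Ovgp1 against 4.93 to 7.53 in the other control libraries. The fat list had 3.4 mean log2 CPM in control library C against -0.493 to 0.0183 in the 3 dose 1 libraries. Mfsd4a (2.78 ± 0.34), Parvb (2.29 ± 0.30), H2-M5 (uncertain, 2.52 ± 0.34), Tbc1d30 (1.91 ± 0.27) and the oxytocin receptor Oxtr (1.95 ± 0.29) had the smallest p and did not pass (smallest adjusted p = 0.247). In all, 0 genes passed in edgeR and 904 had an unadjusted p under 0.05, against 858 by chance. DESeq2 called 78.

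At dose 2 in the F1 ovary, oocyte genes were lower (adjusted p = 1.09e-12, adjusted p = 0.926 with an estimated correlation). Zp3 -0.77 ± 0.20 and Khdc3 -0.85 ± 0.22 were among its 30 members, of which 0 passed over all genes and 9 adjusted over the list alone. Heat shock genes were lower (adjusted p = 6.40e-07, adjusted p = 0.94 with an estimated correlation). Hspa1a (uncertain) -3.05 ± 0.41 and Dnajb1 -1.06 ± 0.19 were among its 16 members, of which 0 passed over all genes and 5 adjusted over the list alone. Immediate early genes were lower (adjusted p = 5.50e-05, adjusted p = 0.135 with an estimated correlation). Jun -0.90 ± 0.16 and Gadd45b -0.85 ± 0.16 were among its 21 members, of which 0 passed over all genes and 3 adjusted over the list alone. Ribosomal protein genes were lower (adjusted p = 1.05e-20, adjusted p = 0.94 with an estimated correlation). 0 of 83 members passed over all genes and 0 adjusted over the list alone. Antioxidant genes were lower (adjusted p = 0.0138, adjusted p = 0.94 with an estimated correlation). 0 of 27 members passed over all genes and 0 adjusted over the list alone. Endothelial genes were higher (adjusted p = 0.0282, adjusted p = 0.94 with an estimated correlation). 0 of 16 members passed over all genes and 0 adjusted over the list alone. Oviduct genes were higher (adjusted p = 0.00415, adjusted p = 0.94 with an estimated correlation). 0 of 16 members passed over all genes and 8 adjusted over the list alone. Ovgp1 stood at 1010, 295 and 3.38 CPM in libraries A, B and C of dose 2, at 3.27 to 3.77 in dose 1 and at 144, 7.53 and 4.93 in controls. Hspa1a (-3.05 ± 0.41), Dhdh (0.96 ± 0.16), Bag3 (-0.67 ± 0.11), Pcolce2 (-1.85 ± 0.32) and Dedd2 (-0.78 ± 0.14) had the smallest p and did not pass (smallest adjusted p = 0.407). In all, 0 genes passed in edgeR and 2053 had an unadjusted p under 0.05, against 858 by chance. DESeq2 called 353. The count was 368 without F1 dose 2 C (363 higher and 5 lower), which leaves A and B, the dose 2 libraries with oviduct markers. It was 350 with all 27 libraries. Without the 3 libraries with oviduct markers (control A, dose 2 A and B), a setting chosen after seeing the data, it was 0, but only library C is then left at dose 2, and this says nothing about stability. Doses 1 and 2 differed at 0 genes in edgeR, with 809 at an unadjusted p under 0.05 and 335 by DESeq2. That count was 448 without F1 dose 2 C (440 higher and 8 lower).

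**Figure D3:**
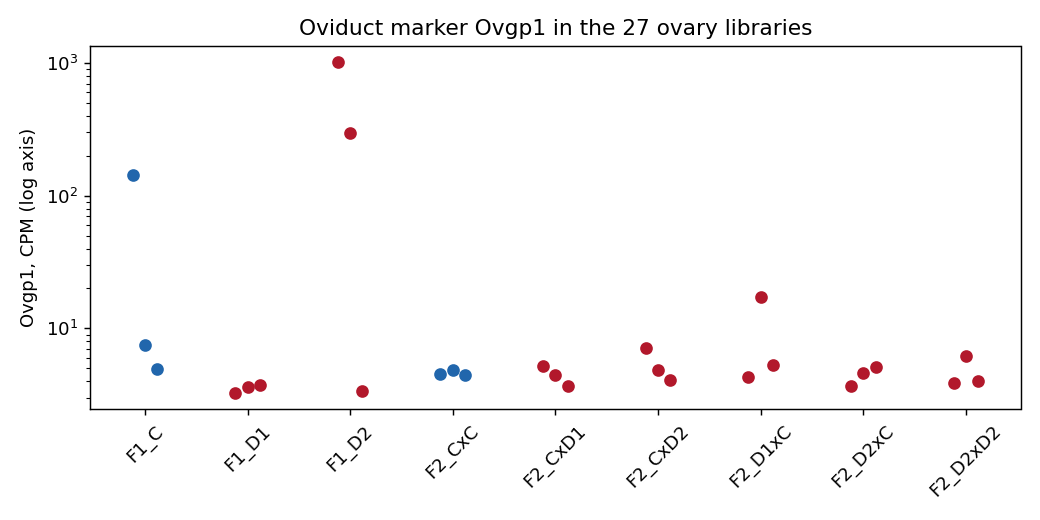
CPM of the oviduct gene Ovgp1 in the 27 ovary libraries on a logarithmic axis, by group, with group codes written male x female. Points are libraries (blue for control groups, red for others): dose 2 libraries A and B and F1 control A stand at 1010, 295 and 144 CPM, and the other 24 lie between 3.27 and 17.4.

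In F2 ovaries with the father at dose 1, cholesterol synthesis genes were higher (adjusted p = 5.02e-12, adjusted p = 0.531 with an estimated correlation). Tm7sf2 1.70 ± 0.50, Lss 1.49 ± 0.48 and Sqle 1.31 ± 0.45 were among its 25 members, of which 0 passed over all genes and 10 adjusted over the list alone. Luteal genes, of the progesterone-producing corpus luteum, were higher (adjusted p = 4.10e-05, adjusted p = 0.434 with an estimated correlation). Oestrous stages of the females are not given and were untested. Star 2.12 ± 0.80 and Scarb1 1.00 ± 0.34 were among its 20 members, of which 0 passed over all genes and 0 adjusted over the list alone. Periovulatory genes were lower (adjusted p = 0.00491, adjusted p = 0.632 with an estimated correlation). Areg -3.28 ± 0.94, Ereg -3.06 ± 0.91 and Ptgs2 -3.51 ± 1.12 were among its 20 members, of which 0 passed over all genes and 3 adjusted over the list alone. Oocyte genes were lower (adjusted p = 5.44e-11, adjusted p = 0.531 with an estimated correlation). Zp2 -0.33 ± 0.11 and Padi6 -0.42 ± 0.13 were among its 30 members, of which 0 passed over all genes and 0 adjusted over the list alone. The piRNA pathway, granulosa cell, cell cycle, chromatin enzyme, heat shock and peritubular lists were lower and the endothelial and antioxidant lists higher. Their adjusted p ran from 9.02e-04 to 0.0472, and from adjusted p = 0.531 to 0.862 with an estimated correlation. Dctn3 (1.49 ± 0.25), Sts (0.86 ± 0.16), Tcp11l2 (0.37 ± 0.072) and Dok7 (-0.73 ± 0.15) were among the 5 smallest p and did not pass (smallest adjusted p = 0.304). In all, 0 genes passed in edgeR and 1681 had an unadjusted p under 0.05, against 873 by chance. DESeq2 called 82. The count was 1 without father dose 1 C.

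With the mother at dose 1, cholesterol synthesis genes of the ovary were higher (adjusted p = 3.17e-05, adjusted p = 0.724 with an estimated correlation). 0 of 25 members passed over all genes and 1 adjusted over the list alone. Luteal genes were higher (adjusted p = 0.00229, adjusted p = 0.724 with an estimated correlation). Star 2.48 ± 0.81 was among its 20 members, of which 0 passed over all genes and 0 adjusted over the list alone. Endothelial genes were higher (adjusted p = 6.04e-06, adjusted p = 0.724 with an estimated correlation). Tie1 0.57 ± 0.18 was among its 16 members, of which 0 passed over all genes and 2 adjusted over the list alone. Periovulatory genes were lower (adjusted p = 0.00743, adjusted p = 0.724 with an estimated correlation). Ereg -3.13 ± 0.91 and Areg -3.15 ± 0.93 were among its 20 members, of which 0 passed over all genes and 2 adjusted over the list alone. The oocyte, peritubular, interferon, surface epithelium and piRNA lists were lower and the fat list higher. Their adjusted p ran from 5.28e-05 to 0.0461, and from adjusted p = 0.724 to 0.9 with an estimated correlation. The fat list had a mean log2 CPM of -0.533, 2.72 and 2.57 in mother dose 1 A, B and C and 0.526, -0.589 and 0.951 in control parents. The interferon response list stood at 3.53, 2.82 and 2.74 against 4.71, 2.98 and 3.09 in control parents A, B and C. Dctn3 (1.44 ± 0.25), Lims2 (0.88 ± 0.17) and the multi-copy, uncertain Ccl27a (1.45 ± 0.25) were among the 5 smallest p and did not pass (smallest adjusted p = 0.282). Ifnl3 (uncertain), also among them, stood at 2.11 ± 1.78 against 0.0229 ± 0.0232 CPM (adjusted p = 0.302). In all, 0 genes passed in edgeR and 1606 had an unadjusted p under 0.05, against 873 by chance. DESeq2 called 122. The count was 68 and 1 without mother dose 1 A and C, and 3 without control parents A. It was 2 with all 27 libraries.

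With the mother at dose 2, granulosa cell genes were lower (adjusted p = 1.66e-05, adjusted p = 0.196 with an estimated correlation). Inhba -1.01 ± 0.33, Fshr -0.53 ± 0.19 and Cyp19a1 -1.63 ± 0.68 were among its 21 members, of which 0 passed over all genes and 0 adjusted over the list alone. Cyp19a1 is aromatase. Extracellular matrix genes were higher (adjusted p = 2.76e-07, adjusted p = 0.533 with an estimated correlation). Mgp 0.48 ± 0.18 and Fn1 0.40 ± 0.17 were among its 30 members, of which 0 passed over all genes and 0 adjusted over the list alone. The oocyte, ribosomal protein, cell cycle and piRNA lists were lower and the peritubular list higher, with adjusted p from 1.40e-05 to 0.0339 and adjusted p = 0.841 with an estimated correlation for each. Kank2 (0.29 ± 0.058), Mri1 (-0.38 ± 0.078), Itga10 (0.57 ± 0.12), Gdpd2 (-1.26 ± 0.27) and Napepld (0.82 ± 0.18) had the smallest p and did not pass (smallest adjusted p = 0.731). In all, 0 genes passed in edgeR and 1017 had an unadjusted p under 0.05, against 873 by chance. DESeq2 called 14. The count was 1 without control parents C.

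With the father at dose 2, the secreted factor Metrnl rose 1.96-fold (log2 0.97 ± 0.12, adjusted p = 0.0155) in the ovary, the only gene to pass in edgeR. Oocyte genes were higher (adjusted p = 1.06e-11, adjusted p = 0.962 with an estimated correlation). Npm2 0.54 ± 0.12 and Gdf9 0.49 ± 0.14 were among its 30 members, of which 0 passed over all genes and 10 adjusted over the list alone. Ribosomal protein genes were higher (adjusted p = 8.49e-36, adjusted p = 0.962 with an estimated correlation). Rpl17 0.60 ± 0.14 and Rps25 0.52 ± 0.12 were among its 83 members, of which 0 passed over all genes and 77 adjusted over the list alone. Tbc1d10a (0.49 ± 0.083), Pfkfb2 (-0.60 ± 0.11), Fam117a (0.50 ± 0.092) and the clock gene Arntl (-0.96 ± 0.18) followed and did not pass (adjusted p = 0.165 for each). For this cross, 1 gene passed in edgeR and 2765 had an unadjusted p under 0.05, against 873 by chance. DESeq2 called 341. The count was 108 and 0 without father dose 2 A and B, and 3, 0 and 0 without control parents A, B and C. It was 0 with all 27 libraries. With only the 6 libraries compared, 1 gene passed and it was not Metrnl.

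With both parents at dose 2, the clock transcription factors Dbp (Entrez 13170) and Nr1d1 rose 4.86-fold (log2 2.28 ± 0.39, adjusted p = 0.0391) and 2.83-fold in the ovary. Steroid sulfatase (Sts) rose 1.96-fold (log2 0.97 ± 0.16, adjusted p = 0.0391), the stress-response gene Herpud1 1.72-fold (log2 0.79 ± 0.14, adjusted p = 0.0391) and chemerin (Rarres2) 1.75-fold (log2 0.81 ± 0.13, adjusted p = 0.0391). Increases of Bc1 (uncertain) 3.15-fold, H2aw (uncertain) 1.78-fold, Bambi 1.71-fold, Tspan4 1.69-fold and Igfbp6 1.66-fold passed. Desmoplakin (Dsp) fell 2.72-fold (log2 -1.44 ± 0.28, adjusted p = 0.0453), the splicing regulator Rbm20 2.26-fold (log2 -1.18 ± 0.19, adjusted p = 0.0391) and the potassium channel Kcnj2 2.45-fold (log2 -1.29 ± 0.27, adjusted p = 0.0474). Decreases of Cntn2 2.83-fold, Olfml2a 2.58-fold, Csrnp3 2.32-fold, Septin3 2.18-fold, Scube1 2.11-fold, Phf24 2.11-fold and Abca5 2.1-fold passed. Ribosomal protein genes were higher (adjusted p = 1.34e-21, adjusted p = 0.939 with an estimated correlation). 0 of 83 members passed over all genes and 72 adjusted over the list alone. Chromatin enzyme genes were lower (adjusted p = 1.44e-04, adjusted p = 0.939 with an estimated correlation). Tet3 -0.60 ± 0.14 and Kdm6b -0.48 ± 0.12 were among its 37 members, of which 0 passed over all genes and 4 adjusted over the list alone. Interferon response genes were higher (adjusted p = 0.0431, adjusted p = 0.939 with an estimated correlation). Ifit3 2.81 ± 0.94 was among its 23 members, of which 0 passed over all genes and 0 adjusted over the list alone. Library C of this group stood at 5.74 mean log2 CPM of the interferon response list against 3.91 and 3.21 in A and B. The heat shock, antioxidant and cholesterol synthesis lists were higher and the peritubular list lower, with adjusted p from 0.0136 to 0.0431 and adjusted p = 0.939 with an estimated correlation for each. In all, 120 of 17454 genes passed (52 higher, 68 lower). The count was 1, 1443 and 0 without both parents dose 2 A, B and C, and 7, 0 and 0 without control parents A, B and C. It was 0 with only the 6 libraries compared, 0 with all 27, 47 without the low-count filter and 1791 by DESeq2.

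The synaptic gene Bsn was 2.66-fold (log2 -1.41 ± 0.19, adjusted p = 0.0275) lower in the ovary with a dose 2 father than with a dose 2 mother, the only gene to pass. There 3559 genes had an unadjusted p under 0.05 and DESeq2 called 872. That count was 9 and 0 without mother dose 2 B and C, and 424, 0 and 0 without father dose 2 A, B and C, and 0 with only the 6 libraries compared. Rbm3 (0.58 ± 0.089), Npm2 (0.67 ± 0.12), Pir (0.73 ± 0.13) and the paralogous, uncertain Acot1 (0.67 ± 0.1) did not pass. Father against mother at dose 1, the dose 2 interaction and F2 against F1 controls gave 0 genes in edgeR. They had 861, 834 and 2479 genes at an unadjusted p under 0.05, and 3, 4 and 118 in DESeq2. Their smallest p belonged to Rbm3 (0.55 ± 0.089), Arhgap8 (3.61 ± 0.64) and Tmem102 (-1.56 ± 0.26), which did not pass. The count for F2 against F1 controls was 16 without F1 control C, and that for father against mother at dose 1 was 1 without mother dose 1 A, and 1 without father dose 1 C. The dose 2 effect differed between F2 and F1 at 1275 genes (753 relatively higher and 522 lower in F2). The stress gene Ddit3 was relatively 3.28-fold (log2 1.71 ± 0.29, adjusted p = 0.0255) higher, Dnd1 3.52-fold and Ltc4s 3.74-fold higher. Kcne2 was relatively 9.06-fold (log2 -3.18 ± 0.94, adjusted p = 0.0474) lower, Adam28 5.23-fold and Zkscan2 5.31-fold lower. Single libraries stood apart in Adam28 and Kcne2, with 3.85, 2.02 and 0.89 CPM of Adam28 in F1 dose 2 A, B and C, of which A and B hold oviduct markers, and 6.06, 21.3 and 3.56 CPM of Kcne2 in control parents. This count was 14, 4 and 812 without F1 dose 2 A, B and C, and 4, 2408 and 1 without both parents dose 2 A, B and C, and 3, 3941 and 4158 without F1 control A, B and C, and 1, 3 and 1 without control parents A, B and C. It was 0 with only the 12 libraries of these groups, 25 without the low-count filter and 3150 by DESeq2.

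**Figure D4:**
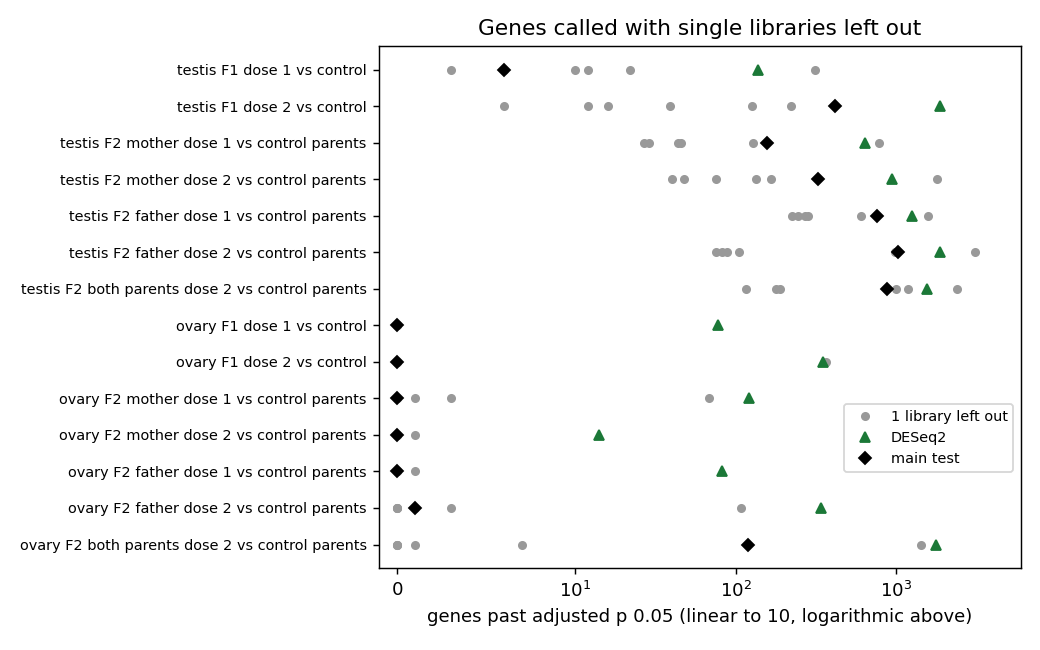
Genes called in each of the 14 comparisons with control, on an axis that is linear to 10 and logarithmic above. Diamonds are the main test, grey points each single library left out and triangles DESeq2: the count for both parents at dose 2 in ovary runs from 0 to 1443 and that for father dose 2 in testis from 75 to 3122.

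Of the lists fixed beforehand, spermatogonia (smallest adjusted p = 0.177), epididymis (0.21), lymphocyte (0.0621), imprinted genes (0.105), theca steroidogenesis (0.516) and neutrophil (0.282) passed in none of the comparisons in which they were tested with the preset correlation.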

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

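The tests of inherited differences between families, of oviduct tissue, of exposure as the source of oviduct markers, of control libraries that stand apart and of interstitial tissue were chosen after the result was seen. The test of reads shared between gene copies and the splits of the libraries were not.

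Several tests of a difference between effects called genes. In testis, father against mother gave 223 genes at dose 1 and 21 at dose 2, and the 10 splits of 6 libraries are too few to go under a share of 0.05. With those 6 libraries alone the counts were 707 against at most 15 in other splits, and 61 against at most 1. The effect of both dose 2 parents differed from the sum of the single-parent effects at 94 genes, and the dose 2 effect in F2 from that in F1 at 2070. For these, the 12 libraries alone gave 57 against at most 4 and 543 against at most 29 over 41 drawn splits, 1 of 41 as large. That decides nothing about chance, since the draws also scatter the differences between single groups, up to 378 and 1465 genes in these libraries, into the spread. The 1465 genes lie between F1 controls and F2 from control parents, while F1 dose 2 and F2 from dose 2 parents differed at 48. In ovary, father against mother at dose 2 gave 1 gene (0 and at most 1 in the splits, too few to go under 0.05). The ovary dose 2 effect differed between generations at 1275 genes, but the 12 libraries alone gave 0 and another split 1, and beside a count of 0 all 41 splits are as large whatever the cause, so they decide nothing. The ovary count was 1 without both parents dose 2 C and 4158 without F1 control C.

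Genes called at 2-fold or more in the F2 testis lay beside each other. Of 519 calls, 11.6% had a neighbour called the same way, against a median of 0.771% and at most 3.08% in 1000 random sets (permutation p = 0.001, the smallest they can give), with 9 of 52 and 35 of 197 for mother and father dose 1 and 4 of 61, 7 of 98 and 5 of 111 for mother, father and both parents at dose 2. Reads shared between near-identical copies are argued against as the whole cause, since 6.84% remained without predicted names and same-stem neighbours against a median of 0.482%. Inherited sequence or copy-number differences between families may account for part, as testis and ovary deviations of the same cross correlated by 0.0952 on average against -0.0191 for other crosses (17 of 720 orders as high, exact one-sided permutation p = 0.0236). An effect of parental exposure on both tissues stays open as well and was untested.

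Oviduct markers were higher in F1 dose 2 ovaries. In the list mean, 2 of the 3 dose 2 libraries lay above every control and dose 1 library, and C lay within the range of dose 1. Oviduct tissue in single libraries and the dose 2 exposure itself cannot be told apart by this, since library C alone would decide. With the first bounds, the tissue test fitted and the exposure test did not, and both bounds were changed for that reason after these labels were seen, so that at least 2 libraries must lie within the range. Control A, which was not exposed, held 144 CPM of Ovgp1.

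Leydig steroidogenesis genes were lower in the 5 F2 crosses with an exposed parent. Control parents libraries that stand apart may account for it, since their list mean was 5.12 against 4.85 in F1 controls, a difference of 0.267 log2 CPM, with generation and handling not separable. A larger share of interstitial tissue in the control parents libraries cannot be told apart from this, because the 5 lists of Leydig, macrophage, endothelial, peritubular and extracellular matrix genes lay lower by amounts at most 1.66 standard errors apart over all crosses. Its first bound of 2 standard errors was replaced after the values were seen by 3.19, the 95% bound of a range of 5 with 12 residual degrees of freedom, and 5 of 7 groupings of crosses exceeded the first bound (highest 2.46, mother dose 1, where macrophage genes moved by 0.0633 ± 0.0838 and extracellular matrix by -0.233 ± 0.123). Parental exposure stays open and was untested.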

How the results depend on the processing

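The settings that leave out several named libraries were chosen after the result was seen, and all other settings were fixed before the data were examined. No named gene reversed its direction, which is nearly ensured by choosing most with libraries that did not overlap. The 161 named genes make 202 pairs of a gene and a comparison. Of 2476 values of these pairs over all settings, 1776 stayed on their side of the threshold, 618 fell below it and 82 came to pass it. All 202 pairs stayed with RLE size factors, and no count of genes moved by over 1.5 times there. DESeq2 moved 49 pairs past the threshold and 0 below it, single libraries left out moved 471 below it and left 853 where they were, and the missing filter moved 31 below it. The cause of these changes was not tested unless stated. A library left out takes a replicate away, and a group left with 2 libraries, or with 1 in the settings that leave out several, is assumed to vary like the others. Depth limits genes with low counts, and the lowest library total was 31.8 M.

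With DESeq2, the count was, in testis 139 for F1 dose 1, 1890 for F1 dose 2, 645 for mother dose 1, 947 for mother dose 2, 1264 for father dose 1, 1879 for father dose 2, 1564 for both parents, 1223 for F1 dose 2 against dose 1, 509 for father against mother at dose 1, 88 for father against mother at dose 2 and 462 for the interaction. In ovary it was 78 for F1 dose 1, 353 for F1 dose 2, 122 for mother dose 1, 14 for mother dose 2, 82 for father dose 1, 341 for father dose 2, 1791 for both parents, 335 for F1 dose 2 against dose 1, 3 for father against mother at dose 1, 872 for father against mother at dose 2, 4 for the interaction, 3150 for the dose 2 effect in F2 against F1 and 118 for F2 against F1 controls. With only the 6 compared libraries in the fit, the count was, in testis 16 for F1 dose 1, 2132 for F1 dose 2, 202 for mother dose 2, 458 for father dose 2 and 120 for both parents. In ovary it was 0 for both parents. Away from controls, the 6 libraries alone gave 3 for F1 dose 2 against dose 1 and 707 and 61 for father against mother at doses 1 and 2 in testis, and 0 for the last in ovary. The 12 libraries alone gave 57 for the testis interaction, and 543 and 0 for the dose 2 effect in F2 against F1 in testis and ovary. With all 27 libraries in the fit, the count was, in testis 27 for F1 dose 1, 1315 for F1 dose 2 and 98 for mother dose 1. In ovary it was 350 for F1 dose 2, 2 for mother dose 1, 0 for father dose 2 and 0 for both parents. Without the low-count filter, where more genes are tested, the count was, in testis 13 for F1 dose 1 and 75 for F1 dose 2 against dose 1. In ovary it was 47 for both parents and 25 for the dose 2 effect in F2 against F1. It was 2758 in testis for both parents without its libraries A and B, a test of library C alone on the spread of the other groups, and 1677 for F1 dose 2 without control C and dose 1 A. Without the 3 libraries with oviduct markers it was 0 for both F1 doses in ovary. At dose 2 only library C is then left, so its 0 says nothing about stability.

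With the replicate letter as a block, the count was, in testis 167 for F1 dose 2, 7 for F1 dose 2 against dose 1 and 11 for father against mother at dose 2. In ovary it was 2 for F1 dose 2, 1 for F1 dose 2 against dose 1, 0 for father against mother at dose 2 and 15 for the dose 2 effect in F2 against F1. The block changed no other count by over 1.5 times. Over all 26 comparisons, the letters pair samples by the check used here for F1 dose 1 in ovary alone, where the count stayed at 0. The check of the 12 that are not with control was made after these counts were seen. In the other 25 the samples share only a letter, although every library correlated best with its own letter for mother dose 1 and father dose 1 in testis and for mother dose 1, father dose 2 and father against mother at dose 2 in ovary. The lists past the threshold with the block numbered 3, 6, 10, 13, 11, 11 and 13 in the testis comparisons with control and 9, 6, 10, 7, 12, 2 and 9 in those of ovary. Without it they numbered 2, 4, 9, 13, 11, 11 and 14, and 8, 7, 10, 7, 12, 2 and 7. With a correlation estimated per list, 1 list passed for mother dose 2 in testis and 0 in each of the other 13 comparisons with control.

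With single libraries left out in turn, the count ran in testis from 3 to 315 for F1 dose 1, 6 to 223 for F1 dose 2, 27 to 785 for mother dose 1, 40 to 1800 for mother dose 2, 224 to 1595 for father dose 1, 75 to 3122 for father dose 2, 116 to 2416 for both parents, 3 to 77 for F1 dose 2 against dose 1, 79 to 273 for father against mother at dose 1, 0 to 47 for father against mother at dose 2, 26 to 1047 for the interaction, 703 to 3420 for the dose 2 effect in F2 against F1 and 574 to 3185 for F2 against F1 controls. In ovary it ran from 0 to 0 for F1 dose 1, 0 to 368 for F1 dose 2, 0 to 68 for mother dose 1, 0 to 1 for mother dose 2, 0 to 1 for father dose 1, 0 to 108 for father dose 2, 0 to 1443 for both parents, 0 to 448 for F1 dose 2 against dose 1, 0 to 1 for father against mother at dose 1, 0 to 424 for father against mother at dose 2, 0 to 0 for the interaction, 1 to 4158 for the dose 2 effect in F2 against F1 and 0 to 16 for F2 against F1 controls. The F1 with F2 correlation of fold changes, none of which passed, ran from -0.112 to -0.0186 for testis F1 dose 2 with mother dose 2, -0.054 to 0.0136 for testis F1 dose 2 with father dose 2, -0.198 to 0.0305 for testis F1 dose 2 with both parents dose 2, -0.117 to 0.0557 for testis F1 dose 1 with mother dose 1, -0.0541 to 0.0307 for testis F1 dose 1 with father dose 1, -0.0666 to 0.0395 for ovary F1 dose 2 with mother dose 2, -0.282 to -0.0819 for ovary F1 dose 2 with father dose 2, -0.26 to 0.0897 for ovary F1 dose 2 with both parents dose 2, 0.147 to 0.294 for ovary F1 dose 1 with mother dose 1 and 0.00423 to 0.278 for ovary F1 dose 1 with father dose 1. With only genes of at least 10 CPM it turned to -5.31e-04 for testis F1 dose 1 with father dose 1 and to 0.039 for testis F1 dose 2 with father dose 2.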

Other observations

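The circadian clock and cold-shock list and the description of its members were chosen after the result was seen, and the splits of the libraries were not.

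A list of 21 clock and cold-shock genes was added after clock genes such as Dbp, Nr1d1 and Arntl were seen in the results, so its tests on the same data are not independent evidence. It was tested by itself in each of the 14 comparisons with control, without adjustment over these, and passed in 4, of which 1 held with an estimated correlation. In the ovary with the father at dose 1 it was higher (p = 8.08e-04 by camera, p = 0.0386 with an estimated correlation). There Dbp was 1.96 ± 0.39, Per3 1.01 ± 0.21 and Tef 0.55 ± 0.13 on the log2 scale and Arntl, which acts in antiphase to them, -0.77 ± 0.18. None passed over all genes, and 8 higher and 3 lower members passed adjusted over the list alone. With both parents at dose 2 the list did not pass by camera, with 3 members, Dbp, Nr1d1 and Tef, higher over all genes. In testis it was higher at F1 dose 2 (p = 0.0455, p = 0.285 with an estimated correlation), where Per3 passed at 0.58 ± 0.096. It was lower with the father at dose 1 (p = 0.0414, p = 0.075 with an estimated correlation) and with both parents at dose 2 (p = 0.0339, p = 0.0654 with an estimated correlation), and Bhlhe40 fell in both, by 0.93 and 0.95 on the log2 scale. The hour at which tissues were taken is not given in the sources used here, and no explanation was tested.

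In each comparison of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. With the 6 libraries alone, the testis counts of genes were 16 for F1 dose 1 (highest other split 6), 2132 for F1 dose 2 (0), 220 for mother dose 1 (0), 202 for mother dose 2 (1), 743 for father dose 1 (0), 458 for father dose 2 (0) and 120 for both parents (0). They were 3 for F1 dose 2 against dose 1 (1) and 2452 for F2 against F1 controls (0). In ovary the counts were 0 for F1 dose 1 (0), F1 dose 2 (0), mother dose 1 (3), mother dose 2 (2), father dose 1 (1), both parents (1), F1 dose 2 against dose 1 (0), father against mother at dose 1 (2) and F2 against F1 controls (1), and 1, a gene other than Metrnl, for father dose 2 (0). For the ovary interaction, all 41 drawn splits gave as many genes as the real 0 (highest other 1), as any split must, so this decides nothing.

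The splits were also counted for lists past the threshold with the preset correlation. In testis, 9, 4, 1, 2, 2, 1 and 1 of the 10 splits gave as many lists as the real one for F1 dose 1, F1 dose 2, mother dose 1, mother dose 2, father dose 1, father dose 2 and both parents. The real and highest other numbers were 2 and 6, 5 and 8, 10 and 5, 13 and 14, 9 and 9, 13 and 8, and 14 and 9. In ovary, 4, 9, 10, 6, 3, 10 and 7 of 10 did so, with 10 and 15, 7 and 15, 8 and 14, 9 and 14, 12 and 13, 2 and 12, and 8 and 11.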
